A study of Mus musculus with 6 samples.

How the data were processed

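Bulk RNA-seq was made from CD4+ T cells sorted from C57/B6 mouse spleen cells, with 3 unstimulated libraries and 3 libraries after 1 µg/ml ConA for 48 h. Per the labels' protocols, mRNA was selected by its poly-A tail and copied with random hexamers. Groups came from the treatment labels of the samples, and replicate numbers from the sample titles. The submitters' processing notes name the mouse builds GRCm38 and mm10 and the tools STAR, featureCounts and limma, without versions, roles or order. Strand use in counting was not given in the sources used here.

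The deposited table held a normalised signal for 16823 genes in 6 libraries and a log2 fold change by the authors. All 16823 symbols matched a RefSeq gene table of GRCm38.p6, of which 12951 were protein coding. Each deposited signal value was a whole multiple of a step constant within its library (100% of values within a tolerance of 0.001). The step equalled the reciprocal of a median-of-ratios size factor computed over these genes. The step was set as the smallest value of a library divided by 2, which makes the smallest multiple 2 in each library. Genes below this level in any library were not analysed here, and a gene silent in 1 group could be missing. The multiples summed to 22363331, 26956760 and 25950510 for unstimulated replicates 1, 2 and 3 and to 26489952, 27705892 and 27167188 for ConA replicates 1, 2 and 3. Of multiples below 12, 67.4% to 72.7% were even, against 50.4% to 51.7% of those from 100, so a step may not be 1 read, both mates of a pair may have been counted, and the sums are read depths only with that limit. Sums of the scaled values were 1.24 times higher in ConA. Mitochondrial genes took 1.62% to 2.04% of these sums and the 10 most abundant genes 4.46% to 5.10%.

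Values were transformed as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with group as the only factor and a mean-variance trend. The minimum mean of 1 in at least 1 group removed 0 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all 16823 genes and a threshold of 0.05, and a second count required a log2 fold change of at least 1. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Exact permutation of 3 against 3 libraries cannot give a p below 0.1, the smallest it allows. The first principal component held 84.2% of the variance, and correlations of log2 values across genes, which are not independent replicates, were 0.985 to 0.987 within groups and 0.896 to 0.903 between them.

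Gene lists were fixed before the data were examined: 36 lists with 540 genes, of which 497 were measured. They were tested with camera at a preset correlation of 0.01, adjusted over the 36 lists, which called 14 higher and 11 lower. With an estimated correlation camera called 1 list higher and 0 lower (5 and 4 at an unadjusted p under 0.05). By fry, which asks whether a list's own genes move and compares them with no other genes, 34 lists moved one way on balance and 32 changed in either direction. Adjusted over the list alone, counts of members were the same as over all genes except for T cell activation markers (13 rose), inhibitory receptors (6 rose) and dissociation genes (2 rose).

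Named genes followed a rule also fixed before the data were examined. It took the 10 largest called rises and falls among genes whose groups did not overlap and whose higher mean was above the median, without predicted genes or receptor segments. It added up to 3 called rises and 3 called falls per list, the 3 most abundant members of each list of another cell type, and a set of genes given in advance such as Cd4, Il2ra, Hspd1 and H2-T23. Cd8a and Fas were in that set. Some genes covered by the rule are not reported here.

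On simulated values for 16823 genes with 200 changed, the same limma test found 70.1% of 1.5-fold, 85.1% of 2-fold and 89.4% of 4-fold changes, and 4.12% of its calls were unchanged genes. The real comparison called 70.2% of genes, and its sums of scaled values differed between groups, so these rates may not carry over to it. The authors' deposited table gave a log2 fold change of the same sign for 16797 genes (99.8%), with a median absolute difference of 0.014. Alternatives covered the replicate number as a block, each library left out, filters, pseudocounts, scalings, variance models and list tests. A planned count-model test was left out because it was held uncertain whether the multiples were whole read counts. The smallest multiple of 2 came from how the step was set and is no evidence on this. Figures were drawn with matplotlib.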

Results

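Messenger RNA was sequenced from CD4+ T cells sorted from spleen cells of C57/B6 mice, in 3 libraries of unstimulated cells and 3 libraries of cells from cultures given 1 µg/ml ConA for 48 h. ConA, or concanavalin A, is a plant lectin that binds sugars on surface proteins and activates T cells. The whole spleen cell suspension was stimulated, and CD4+ cells were sorted afterwards. The values were whole multiples of 1 step per library, and summed to between 22363331 and 26956760 steps per unstimulated library and between 26489952 and 27705892 per ConA library over 16823 listed genes. Whether 1 step was 1 read is uncertain, because 67.4% to 72.7% of multiples below 12 were even, so both mates of a pair may have been counted. Values are called normalised reads with that limit. The labels gave the unstimulated libraries a time of 0 h and did not say whether those cells were kept in culture, so time in culture was not separable from ConA. They also did not say whether libraries of a group came from separate animals or cultures, so p-values measured the spread between these libraries, which may be technical.

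The comparison asked how gene expression in CD4+ T cells differed before and after activation. After ConA, genes of cell division, glycolysis, sterol synthesis, ribosome assembly and protein folding were higher, and genes of resting T cells were lower. These list calls used a preset correlation, and with an estimated correlation they were lost (adjusted p = 0.114 to 0.189), except for S phase genes (adjusted p = 0.0417). Il2ra, the alpha chain of the IL-2 receptor, rose 16.6-fold. It went from 2151 ± 286 to 35485 ± 2250 normalised reads (mean ± SD, n = 3 per group). Mki67, a marker of dividing cells, rose 4.82-fold, and Klf2, a transcription factor of resting T cells, fell by 3.92 on the log2 scale, from 12373 ± 482 to 816 ± 85.7. Markers of macrophages, neutrophils, B cells and NK cells were also lower in the ConA libraries, with a median log2 fold change of -6.60 for the monocyte and macrophage list. The camera calls of these 4 lists were likewise lost with an estimated correlation (adjusted p = 0.114 to 0.200). Cd4 itself stood at 15894 ± 748 in unstimulated and 13912 ± 262 in ConA libraries.

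By limma on log2(value + 1) with Benjamini-Hochberg adjustment, 5958 genes were higher and 5847 lower in ConA at an adjusted p under 0.05, and 5018 did not pass. A change of at least 2-fold was present in 3027 of the higher and 3387 of the lower genes. The groups did not overlap in 72.8% of genes, where 10% would do so by chance. Of the calls 50.5% were higher, and 37.0% were higher (4457 genes against 7575) when each library was instead divided by its total over the listed genes, a scaling chosen after seeing the data that moved the median of all genes by -0.31.

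**Figure D1:**
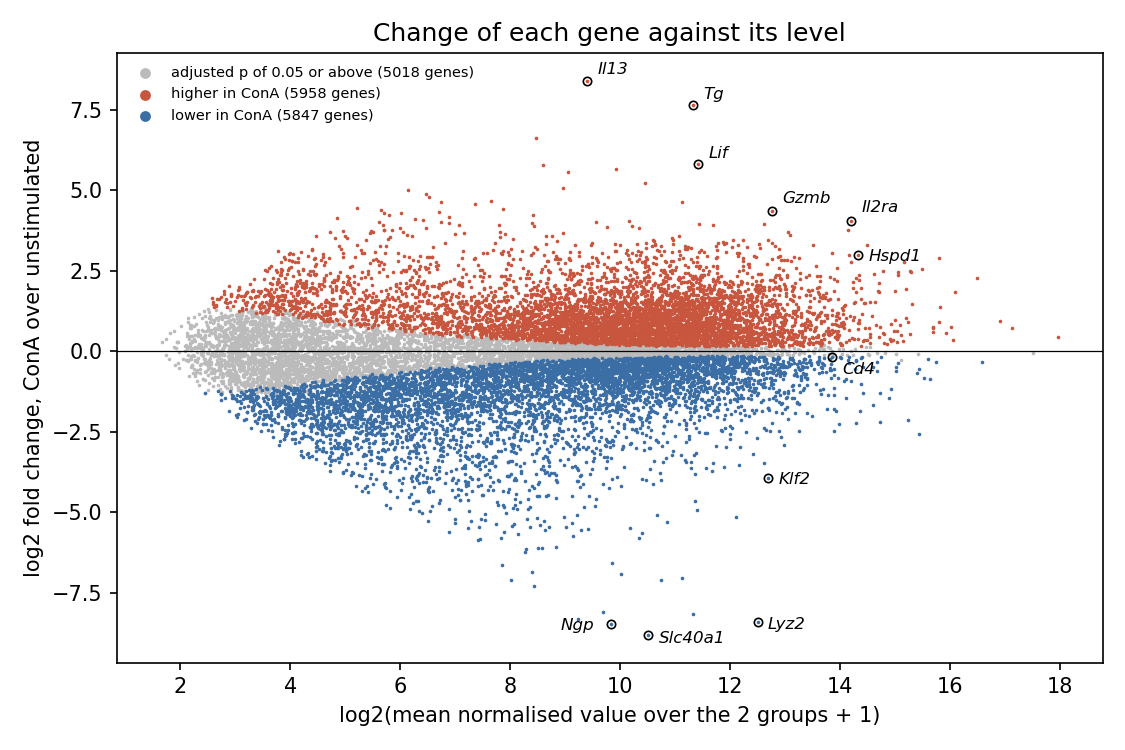
Log2 fold change of each of the 16823 genes (y axis) against the log2 of its mean normalised value plus 1 (x axis). Red points are the 5958 genes higher in ConA, blue points the 5847 lower and grey points the 5018 that did not pass, and Il13 and Slc40a1 lie at the extremes of 8.40 and -8.81 among the named genes.

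The named gene with the greatest rise was Il13, a type 2 cytokine, at a log2 fold change of 8.40 (adjusted p = 8.2e-14 by limma), from a base of 3.14 ± 1.26 normalised reads to 1353 ± 168. Next was Tg, which encodes the thyroid hormone precursor thyroglobulin, at 7.65, from 25.3 ± 7.47 to 5117 ± 194 (chromosome 15, 66670754 to 66850721, GRCm38). Sla lies inside Tg on the other strand, and the sources used here did not state whether counting used strand. Il22 (6.63), the IL-6 family cytokine Lif (5.80), the kinase gene Dclk1 (5.77) and the protease inhibitor gene Serpine2 (5.65) followed. Tnip3 (5.56), the branched-chain aminotransferase gene Bcat1 (5.23), Ajuba (5.08) and Lad1 (4.62) also rose. Among genes that met the naming rule, the iron exporter gene Slc40a1 fell by 8.81 on the log2 scale, the most of any, followed by Ngp (-8.46), Lyz2 (-8.42), Adgre4 (-8.31), Csf1r (-8.17), Mrc1 (-8.09), Hp (-7.30), Vcam1 (-7.10), Fn1 (-7.04) and Csf3r (-6.91). Lyz2, Csf1r and Vcam1 belong to the monocyte and macrophage list (median -6.60), and Ngp and Csf3r to the neutrophil list (median -6.91). The others were in neither of these short lists, which does not show that macrophages or neutrophils lack them. Whether these falls took place in T cells or came from other cells was not tested.

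Genes of the cell cycle rose together. All 22 S phase genes rose, with a median log2 fold change of 2.55, among them the replication licensing gene Cdc6 (3.44), Gins2 (3.36) and the ribonucleotide reductase gene Rrm2 (3.35). The list was higher by camera (adjusted p = 5.1e-14) and was the only list still called with an estimated correlation (adjusted p = 0.0417 with an estimated correlation). All 20 G2 and M phase genes rose, with a median of 2.81, led by Ccnb1 (3.37), Cdk1 (3.24) and Aurkb (3.18), and the list was higher by camera (adjusted p = 2.4e-13, but adjusted p = 0.168 with an estimated correlation).

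Metabolic genes followed the same direction. In glycolysis 16 of 18 genes rose, with a median of 2.44, including Hk2 (3.95), Tpi1 (3.62) and Pgam1 (3.09), while the glucose transporter gene Slc2a3 fell by 0.25 and lost its call when libraries were centred on the median gene (camera adjusted p = 1.5e-09, and adjusted p = 0.168 with an estimated correlation). All 22 genes of the TCA cycle and respiratory chain rose, by a median of 1.08, with Cycs at 2.14 and Idh3a at 1.77 (camera adjusted p = 1.5e-09, and adjusted p = 0.114 with an estimated correlation). In one-carbon, serine and nucleotide synthesis 18 of 19 genes rose, with a median of 2.24 and Shmt1 (3.26), Psat1 (3.22) and Phgdh (2.82) in front (camera adjusted p = 2.8e-11, and adjusted p = 0.114 with an estimated correlation). In amino acid transport and use 15 of 16 genes rose, with a median of 1.74, among them Bcat1, the polyamine enzyme gene Odc1 (3.75) and the leucine transporter gene Slc7a5 (3.19), at a camera adjusted p of 2.1e-07 and adjusted p = 0.114 with an estimated correlation. All 20 genes of cholesterol and lipid synthesis rose, with a median of 2.21, led by Idi1 (3.53), Fdps (3.37) and Cyp51 (3.30), at a camera adjusted p of 7.7e-12 and adjusted p = 0.189 with an estimated correlation. Of the 10 mitochondrially encoded genes 6 rose, with ND1 at 0.74 and ND2 at 0.63. That list was not called (camera adjusted p = 0.0798), except without unstimulated replicate 1 (adjusted p = 0.0259).

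Genes for making and folding proteins were higher as well. All 20 ribosome biogenesis genes rose, with a median of 1.86, including the nucleolar protein genes Ncl (2.55) and Npm1 (2.37), at a camera adjusted p of 2.8e-11 and adjusted p = 0.114 with an estimated correlation. Of 24 cytosolic ribosomal protein genes 23 rose and Rps24, not called when centred on the median gene, fell, with a median of 0.40 and Rps2 at 1.46. Only 8 rose after quantile normalization, where the median was -0.04 and the list was not called, and 9 rose under scaling to the total (median 0.085). The list's camera adjusted p was 6.2e-05, and adjusted p = 0.304 with an estimated correlation. Processed copies of ribosomal protein genes could share reads with them. Among 24 chaperone and unfolded protein response genes 23 rose, with a median of 1.66. The mitochondrial chaperone gene Hspd1 rose from 4610 ± 440 to 36793 ± 1801, followed by Hsp90aa1 (2.47) and Hspa9 (2.34), while the stress-induced gene Ddit3 fell by 0.45, a call lost with unequal variances (adjusted p = 0.0654). The camera adjusted p of the list was 1.2e-10, and adjusted p = 0.168 with an estimated correlation.

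**Figure D2:**
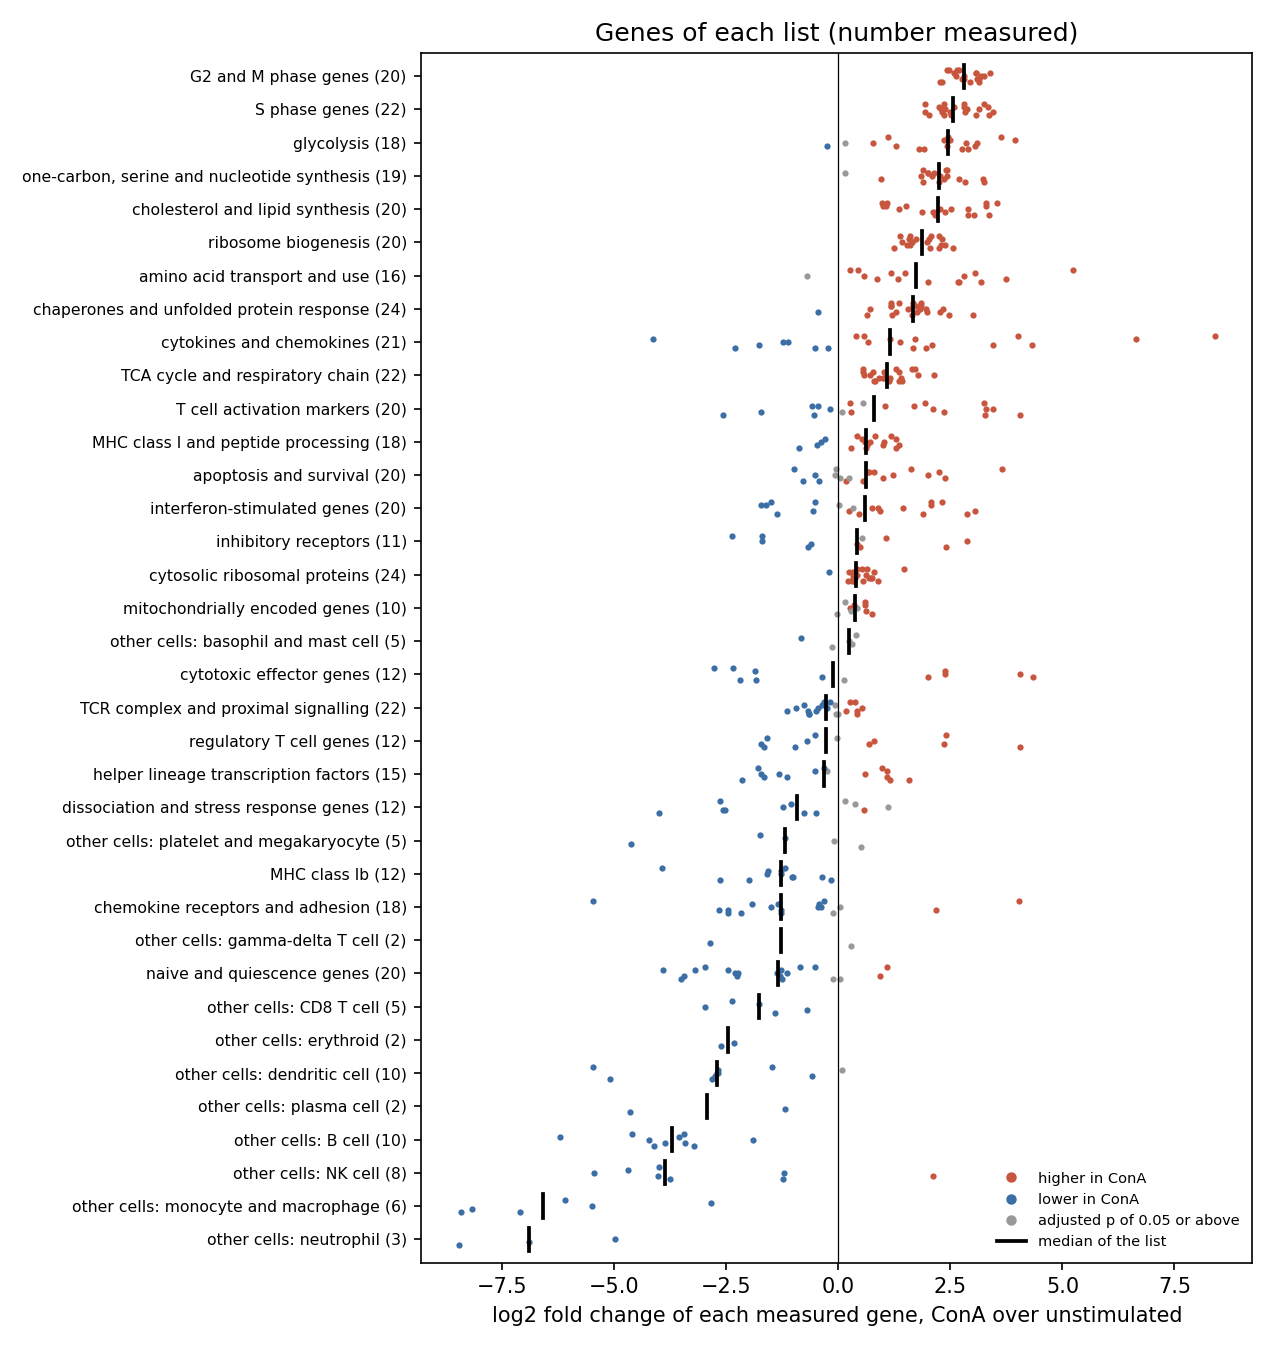
Log2 fold change of each measured gene (points, x axis) in the 36 lists (y axis, number of genes measured in parentheses), with the median of each list as a bar. Red and blue points passed the test as higher and lower in ConA, and the medians run from -6.91 for neutrophil markers to 2.81 for G2 and M phase genes.

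Among 20 T cell activation markers 12 rose and 6 fell. Il2ra, the transcription factor gene Irf4 (3.44) and the transferrin receptor gene Tfrc (3.30) rose, and Cd38 (-2.58), Cd24a (-1.72) and Cd40lg (-0.60) fell. B cells also express Cd38 and Cd24a, and all 10 B cell markers were lower in the same libraries (median -3.71). The activation list was higher by camera (adjusted p = 0.00744, and adjusted p = 0.189 with an estimated correlation). The early activation marker Cd69 was higher by 0.29 on the log2 scale (adjusted p = 0.00195 by limma), was not called after quantile normalization, and stood at -0.03 with no call under scaling to the total. The memory marker Cd44 was lower by a log2 fold change of -0.19 (adjusted p = 0.0155 by limma), a call lost without unstimulated replicate 1 (adjusted p = 0.0623), when centred on the median gene (0.158), without a mean-variance trend (0.0707) and with unequal variances (0.0648). The Cd4 call (log2 fold change -0.19, adjusted p = 0.00877 by limma) was lost without ConA replicate 2 (adjusted p = 0.0549), when centred on the median gene (0.137) and without a mean-variance trend (0.0621).

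Of 20 naive and quiescence genes 16 fell and 2 rose, with a median of -1.34. Klf2, the egress receptor gene S1pr1 (-3.52) and Tsc22d3 (-3.45) fell furthest, and Satb1 (1.08) and the lymph node homing receptor gene Ccr7 (0.94) rose. The list was lower by camera (adjusted p = 2.0e-07, and adjusted p = 0.114 with an estimated correlation), while the monocyte and macrophage markers had a median of -6.60 in the same libraries. In chemokine receptors and adhesion 14 of 18 genes fell, among them Cx3cr1 (-5.47), which monocytes and NK cells also express, Cxcr4 (-2.68) and the integrin gene Itga4 (-2.47), whereas Ccr8 (4.03) and Ccr4 (2.17) rose. That list was lower by camera (adjusted p = 0.000437, and adjusted p = 0.189 with an estimated correlation).

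Of 21 measured cytokine and chemokine genes 14 rose and 7 fell, and camera did not call the list (adjusted p = 0.128). Besides Il13 and Il22, Il17f rose by 4.32, Ifng 10.9-fold from 256 ± 15.4 to 2849 ± 668, and Il2 from 25.8 ± 9.63 to 98.3 ± 6.50. Ccl5 (-4.13), Xcl1 (-2.30) and Ccl3 (-1.77) fell, all of which NK cells also make. In the cytotoxic effector list 5 genes rose, led by Gzmb, the granzyme B gene, from 656 ± 55.7 to 13287 ± 819 (20.2-fold), with Gzmc (4.06) and Serpinb9 (2.38), and 6 fell, including the perforin gene Prf1 (-2.78), Ctsw (-2.36) and Gzma (-2.19). The list was not called (camera adjusted p = 0.997), and its median (-0.12) and mean (0.32) differed in sign. The median ranged from -0.45 after quantile normalization and -0.43 under scaling to the total to -0.077 without unstimulated replicate 1 and -0.046 when centred on the median gene. The NK cell list (median -3.88, 7 of 8 genes lower) and the CD8 T cell list (median -1.78, 5 of 5 lower) were lower in the same libraries. NK cells also express Klrd1 and Klrk1 of the CD8 T cell list, so these lists are not separate evidence. The death ligand gene Fasl rose from 306 ± 34.9 to 1226 ± 148. Its receptor gene Fas stood at a log2 fold change of 0.23 (adjusted p = 0.0891 by limma), at -0.08 under scaling to the total, and was called higher without unstimulated replicate 2 (adjusted p = 0.0243) and when centred on the median gene.

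Of 12 regulatory T cell genes 5 rose and 6 fell. Foxp3, the lineage factor of regulatory T cells, fell from 2351 ± 161 to 747 ± 140, with Ikzf2 (-1.74) and Nrp1 (-1.59), while Il2ra, Ctla4 (2.40) and Tnfrsf18 (2.36), which activated T cells also express, rose. The list was not called (camera adjusted p = 0.997), with a median of -0.28 (-0.18 without ConA replicate 3 and -0.59 under scaling to the total) and a mean of 0.25. Of 15 helper lineage transcription factors 6 rose, led by Tbx21 (1.58), Runx3 (1.15) and Stat4 (1.09), and 8 fell, led by Bcl6 (-2.14), without a call for the list (camera adjusted p = 0.561). Of 11 inhibitory receptors 5 rose, with Lag3 at 2.87, and 5 fell, with Vsir at -2.38 and Tigit at -1.71. That list was not called (camera adjusted p = 0.997), and the sign of its camera test was opposite to that of its median (0.42) and mean (0.063). The median was 0.17 after quantile normalization and 0.11 under scaling to the total.

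Of 22 genes of the TCR complex and proximal signalling 13 fell and 6 rose, with a median of -0.28, after quantile normalization 17 fell and 0 rose (median -0.62), and under scaling to the total 16 fell and 1 rose (median -0.59). The CD3 chain gene Cd3g (-0.95) and the kinase gene Fyn (-0.76) were among those that fell. The camera call was marginal (adjusted p = 0.0456, and adjusted p = 0.512 with an estimated correlation). It was lost with the replicate number as a block (adjusted p = 0.0741), without unstimulated replicate 2 (0.0760), ConA replicate 1 (0.0526), ConA replicate 2 (0.0663) or ConA replicate 3 (0.0554), and when centred on the median gene (0.0971).

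The series title concerns self-reactive CD8+ T cells, and genes of MHC class I presentation were among the fixed lists. Of 18 class I and peptide processing genes 14 rose, including the proteases Ide (1.34) and Psmb8 (1.29) and the disulfide isomerase gene Pdia3 (1.28), and Erap1 rose by 0.60. The 4 that fell included the class I heavy chains H2-K1 (-0.88) and H2-D1 (-0.49) and the light chain gene B2m (-0.38). The list was higher by camera (adjusted p = 0.00602, and adjusted p = 0.189 with an estimated correlation), but not after quantile normalization (adjusted p = 0.176). All 12 measured MHC class Ib genes fell, with a median of -1.27, led by H2-Q10 (-3.93), Cd1d1 (-2.64) and H2-Q2 (-1.99), beside the median of -6.60 for monocyte and macrophage markers. Camera called the class Ib list lower (adjusted p = 1.8e-05, and adjusted p = 0.114 with an estimated correlation). Several class Ib genes are near copies of each other, so their single values are uncertain. H2-T23, which encodes Qa-1, stood at 6664 ± 192 and 5939 ± 358, a log2 fold change of -0.17 (adjusted p = 0.0278 by limma). This call was lost without unstimulated replicate 1 (adjusted p = 0.0618), unstimulated replicate 2 (0.0746), ConA replicate 2 (0.0538) or ConA replicate 3 (0.133), and when centred on the median gene (0.243). It was also lost with the replicate block (0.0706), without a mean-variance trend (0.113) and with unequal variances (0.0968).

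**Figure D3:**
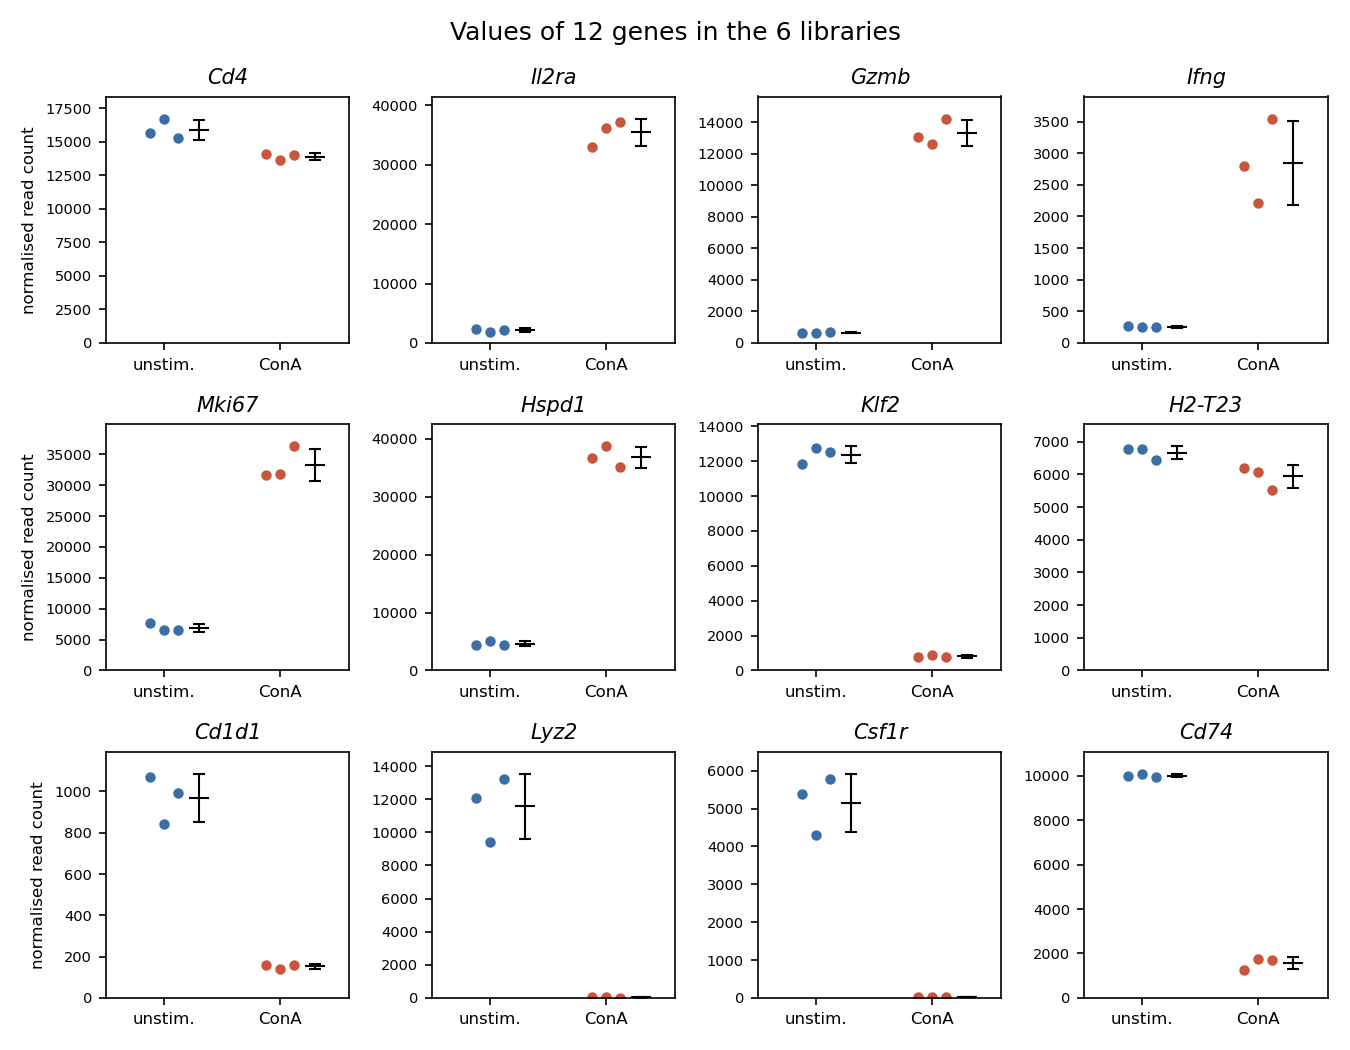
Normalised read counts (y axes, from 0) of 12 genes in the 3 unstimulated (blue) and 3 ConA (red) libraries, with the mean and SD of each group in black. Il2ra, Gzmb, Ifng, Mki67 and Hspd1 were higher in every ConA library, Klf2, Cd1d1, Lyz2, Csf1r and Cd74 were lower, and the means of Cd4 and H2-T23 lay close together (15894 and 13912 for Cd4).

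Of 20 interferon-stimulated genes 12 rose, led by the GTPase genes Iigp1 (3.05), Gbp2 (2.86) and Igtp (2.31), and 6 fell, including Rsad2 (-1.74), Irf7 (-1.61) and Rtp4 (-1.50). The camera adjusted p was 0.0313, and adjusted p = 0.200 with an estimated correlation, and the list was not called after quantile normalization (adjusted p = 0.104). Of 20 apoptosis and survival genes 12 rose, with Cdkn1a (3.66) and the survival gene Bcl2l1 (2.38), and 4 fell, including Bbc3 (-0.998), Cflar (-0.79) and Mcl1 (-0.53). The camera adjusted p was 0.0308, and adjusted p = 0.189 with an estimated correlation, and the call was lost after quantile normalization (0.255) and under scaling to the total (0.0775). Of 12 dissociation and stress response genes 8 fell, led by the immediate early gene Fos (from 3214 ± 208 to 202 ± 30.9), Dusp1 (-2.64) and Zfp36 (-2.56), at a camera adjusted p of 0.00426 and adjusted p = 0.284 with an estimated correlation. Atf3 rose by 0.57 (adjusted p = 0.00549 by limma), a call lost under scaling to the total (adjusted p = 0.182), with unequal variances (0.109) and without ConA replicate 2 (0.0529). The highest member, Hspa1a, named after its value was seen, stood at 1.11 (adjusted p = 0.0572 by limma). It was called higher with the replicate block (adjusted p = 0.0450), a pseudocount of 10 (0.0478), after quantile normalization (0.0111), when centred on the median gene (0.0428), where 3 members rose, and without unstimulated replicate 2 (0.0101). Markers of monocytes and macrophages (median -6.60), neutrophils (-6.91) and B cells (-3.71) were lower in the same libraries.

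Markers of other spleen cells were mostly lower in ConA. List medians cover measured members only. Of 12 monocyte and macrophage genes 6 were measured, and all 6 fell (camera adjusted p = 1.1e-05, and adjusted p = 0.114 with an estimated correlation). Lyz2 went from 11579 ± 1951 to 33.2 ± 8.75. Of 10 neutrophil genes only 3 were measured, Ngp, Csf3r and Cxcr2 (-4.98). All 3 fell, with a median of -6.91 (camera adjusted p = 0.00433, and adjusted p = 0.189 with an estimated correlation). All 10 B cell genes fell, with a median of -3.71 and Cr2 at -6.22 (camera adjusted p = 1.2e-05, and adjusted p = 0.200 with an estimated correlation). Of 10 dendritic cell genes 9 fell, including Cd74 (-2.69) and H2-Aa (-2.83), at a camera adjusted p of 7.0e-05 and adjusted p = 0.114 with an estimated correlation. Of 8 NK cell genes 7 fell, among them Klrb1c (-4.03), and Il2rb (2.12), an IL-2 receptor chain that T cells share, rose (camera adjusted p = 0.00337, and adjusted p = 0.197 with an estimated correlation). All 5 CD8 T cell genes fell, with Klrd1 at -2.98 and Cd8a, not called without a mean-variance trend or with unequal variances, at -1.41 (camera adjusted p = 0.00483, and adjusted p = 0.237 with an estimated correlation). Of 5 basophil and mast cell genes only Prss34 passed, at -0.84, and the list, with a median of 0.24 and a mean of -0.010, was not called (camera adjusted p = 0.974). The median of that list was -0.072 under scaling to the total, -0.080 without unstimulated replicate 2 and -0.12 without ConA replicate 3, but 0.41 after quantile normalization and 0.49 without ConA replicate 1, where 2 genes rose and 1 fell in each case. Both measured plasma cell genes (of 7 listed) fell, with Jchain at -4.66. Both measured erythroid genes (of 9 listed), Alas2 (-2.63) and Klf1 (-2.32), fell too. Of 5 platelet genes 3 fell, with Ppbp at -4.63. Of 7 gamma-delta T cell genes 2 were measured. Blk, which B cells also express, fell by 2.86, and Sox13 (0.28) did not pass. Camera did not call the plasma cell (adjusted p = 0.113), erythroid (0.125), platelet (0.269) or gamma-delta T cell (0.430) lists.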

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

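The scaling to the total of listed genes was chosen after seeing the data, and the other alternatives were chosen before the data were examined. Under 18 alternatives the 4 counts of genes stayed within 1.5 times their reported values. Leaving out 1 library at a time gave 5597 to 5837 higher and 5477 to 5698 lower genes, and 2954 to 3012 higher and 3234 to 3393 lower genes at 2-fold or more. The greatest drop in total calls came with unequal variances per gene (4940 higher, 4419 lower). The filter alternative with no minimum is void, because the minimum removed 0 genes. Rescaling by a median of ratios would change nothing, since the deposited values already equal it, and the planned count-model test was not run. For camera with an estimated correlation, 1 list was called higher and 0 lower in place of 14 and 11. A higher correlation was not the whole cause. For S phase and apoptosis genes the estimates (0.0060 and 0.0029) lay below the preset 0.01, yet the camera adjusted p rose. It went from 5.1e-14 to 0.0417 for S phase genes and from 0.0308 to 0.189 for apoptosis genes. The rest of the cause was not tested. The direction and the side of the threshold held for 2629 of 2664 values of named genes under alternatives, while 24 lost and 7 gained a call, and 4 reversed. The reversed values came under scaling to the total, Cd69 at -0.026, Fas at -0.082 and Sla at -0.12, and after quantile normalization, Sla at -0.15. Their cause was not tested, but under scaling to the total the median of all genes moved by -0.31. Without a mean-variance trend Cd4, Cd44, Cd8a and H2-T23 were not called, and with unequal variances Atf3, Cd44, Cd8a, Ddit3 and H2-T23 were not. Rps24 was not called when centred on the median gene. The replicate numbers gave no sign of pairing the samples. Deviations of libraries numbered 1, 2 and 3 correlated at -0.47, 0.081 and -0.30 across genes, and 0 of 6 libraries correlated best with their own number. With 3 libraries per group this check cannot exclude a pairing. With the replicate block 5819 genes were higher and 5697 lower, 3029 and 3380 at 2-fold or more, and 14 lists were higher and 10 lower. The list not called under the block was the TCR complex list (adjusted p = 0.0741), and among named genes H2-T23 was not called (adjusted p = 0.0706 by limma). Exchanging libraries between groups gives 10 splits, too few for a share under 0.05. The real split called 11805 genes, 6414 at 2-fold or more, and 25 lists, each matched in 1 of 10 splits, the real one, and the highest of the other splits called 0 genes, 0 at 2-fold and 20 lists by limma and camera (at most 143 and 114 genes at an unadjusted p under 0.05, against 12144 and 6500). The other splits put libraries of both groups on each side, so part of the group difference stays in them. The rest adds to the spread within each side and holds down their gene calls, so their 0 genes are no measure of chance. At these depths a gene at a few normalised reads, such as Il13 in unstimulated libraries, has a fold change set partly by the pseudocount.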

Other observations

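The classes of RNA and the receptor loci in the first 2 paragraphs here were chosen after their values were seen, as were the tests of a common loss of other cells, of scaling, of Sla and of the genes beside Tg. Of 2384 long non-coding RNA genes tested, 357 were higher and 997 lower in ConA by limma, and 26.4% of their calls were higher. Their median log2 fold change was -0.55, and -0.19 after quantile normalization and -0.85 under scaling to the total. Protein-coding genes were split more evenly, with 5257 higher and 4550 lower of 12951. The share of higher calls among long non-coding RNA genes ranged over the other scalings from 16.5% higher under scaling to the total to 39.9% after quantile normalization. For protein-coding genes the share went from 53.6% to 39.9% under scaling to the total.

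The antigen receptor loci, each counted as 1 gene, were lower in ConA. Tcra fell by 2.01 on the log2 scale, from 18572 ± 1684 to 4586 ± 228 normalised reads (n = 3 per group), while Tcrb fell by 0.32, from 109601 ± 5351 to 87535 ± 4684, and by 0.90 after quantile normalization, 0.64 under scaling to the total and 0.25 when centred on the median gene. Tcrg fell by 1.47. The immunoglobulin loci Igh (-1.47), Igk (-2.32) and Igl (-3.61) fell too, beside a median of -3.71 for B cell markers. Each of these 6 loci stayed lower and called under the 4 other scalings.

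Markers of other spleen cells were lower in ConA. The choice of scaling is argued against, since the monocyte and macrophage median nearest to 0 under another scaling was -6.50. Each scaling rests on the libraries' own values, so none can show a difference in total RNA per cell. The lists did not fall by 1 common amount. The basophil list lay 6.84 log2 units above the monocyte and macrophage list, with members from -0.84 to 0.39 against -8.42 to -2.84. The basophil list was picked after it was seen not to fall. A common loss of all non-T cells that was offset in the basophil genes would give the same values, so this comparison cannot decide on it. Macrophage RNA in the unstimulated libraries, despite the sort for CD4+ cells, stays open as a candidate explanation. A second list of 20 macrophage genes, of which 13 were measured, had a median of -3.99, with 13 of 13 measured members called lower. Lyz2 stood at 11579 normalised reads in unstimulated libraries. Whether carried-over cells, cells that express Cd4 or free RNA may be the source, and whether ConA culture removed them, was not tested.

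All measured MHC class Ib genes were lower in ConA. The sum of 15 H2-K, H2-D, H2-Q, H2-T and H2-M genes also fell, with a log2 fold change of -0.83 (95% interval -0.98 to -0.68). An exchange of reads within this family would leave the sum level, so it is argued against as the source of the sum's fall. H2-K1 (66119 normalised reads) and H2-D1 (38696) held much of the unstimulated sum of 160572. The sum therefore cannot tell whether reads from H2-K1 and H2-D1 set the values of single class Ib genes. The choice of scaling is argued against, with at least 11 of 12 members called lower under each other scaling. All scalings tried rest on the libraries' own values, so a difference in total RNA per cell would not show. A lower share of other cells, which also express class I genes, stays open beside a change within CD4+ T cells by ConA, and neither was tested.

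Tg rose by 7.65 on the log2 scale in ConA. Reads from Sla, which lies inside Tg on the opposite strand, are argued against, since Sla had a log2 fold change of 0.19 (95% interval 0.069 to 0.32; -0.15 after quantile normalization and -0.12 under scaling to the total) and 0 of 17 annotated Sla exons overlap a Tg exon. A rise of most neighbouring genes on chromosome 15 is argued against, since 1 of 7 other listed genes within 500 kb was higher by 1 log2 unit or more and 4 were lower, but a rise shared by Tg and Ccn4 (4.63), which was that gene, stays open. RNA from thyroid tissue cannot be told apart from the other sources, because only Hhex of 12 thyroid genes was listed (-2.28). Transcription of Tg in activated T cells may be the source, as a hypothesis that these values do not test.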
